A study of Rattus norvegicus with 45 samples.

How the data were processed

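The ventral tegmental area (VTA), a midbrain region that holds dopamine neurons, was punched from rats and its polyA RNA sequenced, 45 libraries in all. Per the labels' protocols, rats had taken cocaine (0.5 mg/kg per infusion) or saline by lever press in 6 h sessions over 10 days of extended access. They were then infected in the VTA 24 h after drug taking with 1 of 3 lentiviruses, an empty vector with red fluorescent protein (RFP), wild-type histone H3.3 (WT), or H3.3 with glutamine 5 replaced by alanine (Q5A). They were killed after 30 days of abstinence. Drug and virus came from the labels and made 6 groups of 7 or 8 libraries. The titles named 4 sequencing lanes, and every lane held every group. The labels do not state that each library came from a different animal, so p-values measure the spread between these libraries.

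Each deposited file held raw whole-number counts per gene. Per the file headers, the authors counted reads with featureCounts version 1.6.2 over whole gene bodies, introns included, on the Ensembl release 90 annotation of the Rnor_6.0 genome. The command in the headers had no option for strand, read pairs, multi-mapping reads or overlapping genes. Reads from genes that overlap in position, on either strand, or that have near-identical copies can therefore be lost or misplaced. The submitters' processing notes also name rn6 and DESeq2 version 1.6.3; the aligner is not given in the sources used here. The files hold 32883 genes, named by Ensembl identifier with no symbol.

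No gene symbol could be paired with these identifiers, since the reference table used here matched 0 of them. Genes are therefore given by identifier and Rnor_6.0 position. The 34 gene lists fixed before the data were examined, the check of the H3.3 genes, the symbols in the rule for naming genes, and an alternative with tissue composition as covariates needed symbols and were not run. The naming rule was applied as far as it could be: in each comparison with called genes, the 2 with the largest fold up and the 2 with the largest fold down among called genes with a mean of at least 1 CPM, a count scaled by its library's total. The number per direction was lowered because identifiers had no names. Chromosomes, 1 Mb windows with at least 5 tested genes, gene span and expression level were used to group genes, all chosen after the data were seen.

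Tests used edgeR version 4.0.16 in R version 4.3.3. One quasi-likelihood model (glmQLFit and glmQLFTest) was fitted to all 45 libraries with 6 group means and lane as an additive term, after TMM scaling. Genes were kept by filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 15000 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all tested genes within a comparison. There were 9 pairwise comparisons and 3 interactions. Fold changes are log2, with a standard error (SE) derived from the fold and the test statistic, and levels are TMM-scaled CPM with the SD over libraries. Log2 CPM used a prior count of 2. Gene sets were tested with camera (limma version 3.58.1) at a preset correlation of 0.01 and with an estimated one, and with fry.

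Total counts per library ran from 7673963 to 32381595, with a median of 12216540. The share of mitochondrial counts was 6.05% to 9.03%. The spread between libraries of a group, as the common biological coefficient of variation, was 14.3%. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 4.89. Intervals and floors for genes at 0 cover counting error only, with a floor of 3 counts.

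The test was tried on simulated counts for the 15000 genes, with 200 genes changed. For Q5A vs RFP in cocaine it recovered 80% of genes changed 1.5-fold and 90% of those changed 2-fold, with 4.5% of its calls false. For Q5A vs WT in saline these shares were 76%, 95% and 2.8%, and for cocaine vs saline in RFP they were 81%, 95% and 4.9%. Each gene was drawn independently, so these shares do not cover libraries that differ in many genes at once. On the real counts, splits with shuffled group labels called up to 3, 2 and 218 genes for these comparisons, in the order given. For Q5A vs WT in cocaine, which was not simulated, such splits called up to 534.

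Alternatives fixed before the data were examined were DESeq2 version 1.42.0, no lane term, no filter, a stricter filter of 5 CPM in 7 libraries (12056 genes), RLE scaling, only the groups compared, 3 surrogate variables from sva version 3.50.0, leaving out the 3 libraries whose titles had another form, and leaving out each library. Added after the data were seen were leaving out each lane, leaving out 5 libraries that correlated least with the rest, and thinning every library to 7673963 counts. Those 5 had a median Spearman correlation with the other libraries under 0.983, the median of all libraries minus 3 median absolute deviations. They were cocaine Q5A replicates 1 and 3, saline Q5A replicate 1, cocaine RFP replicate 4 and cocaine WT replicate 4. The Q5A libraries among them score highest in the genes that rose with Q5A, so leaving them out removes part of that difference, whatever its cause. Group labels were shuffled within lanes in 40 splits per set of comparisons, the real one included; 100 had been planned, and computing time limited them to 40. Correlations of fold changes across genes were judged by the same splits, two-sided, with Benjamini-Hochberg adjustment over 9 values. The score tests were run in 3 forms, all chosen after the data were seen: labels exchanged freely, within lanes, and within lanes on lane-adjusted differences, each adjusted over 4 tests.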

Results

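RNA from VTA punches was counted over 15000 genes in 45 rat libraries, to ask what a history of cocaine self-administration leaves in this tissue after 30 days of abstinence and how a histone H3.3 without glutamine 5 alters it. The saline groups held 8 RFP, 7 WT and 7 Q5A libraries, and the cocaine groups 8 RFP, 8 WT and 7 Q5A. Total counts per library ran from 11687467 to 27897012 in saline RFP, 10731850 to 32381595 in saline WT and 9197515 to 19103260 in saline Q5A. They ran from 7673963 to 17005889 in cocaine RFP, 8951129 to 19376446 in cocaine WT and 8687751 to 19702283 in cocaine Q5A. Genes appear by Ensembl identifier because the files do not pair identifiers with names, so the H3.3 genes themselves were not examined here.

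**Figure D1:**
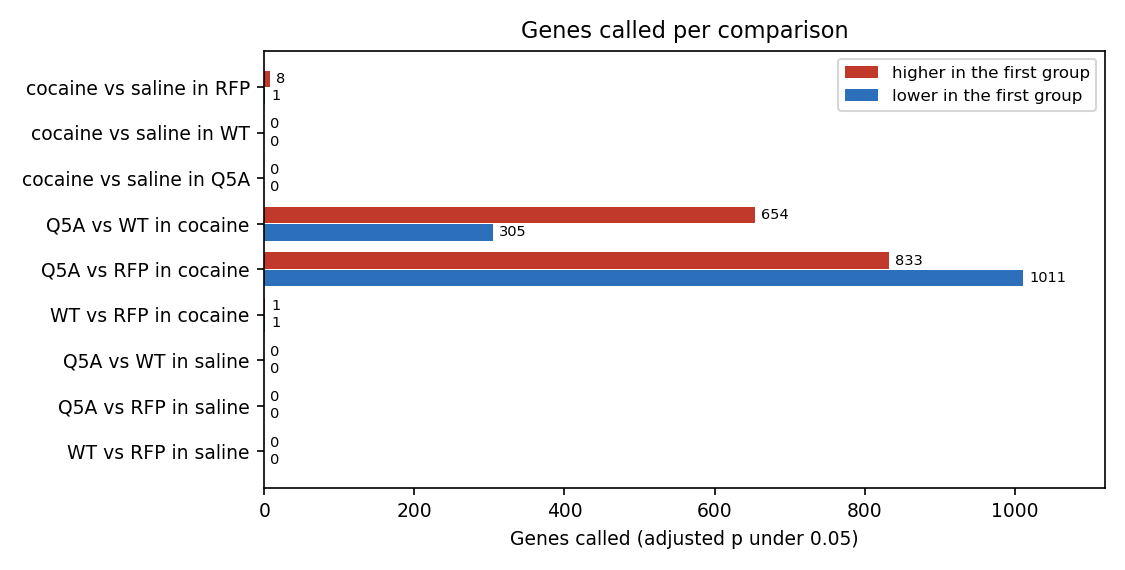
Genes called in each pairwise comparison of groups, by edgeR's quasi-likelihood test at an adjusted p under 0.05, split into those higher (red) and lower (blue) in the group named first. Q5A vs RFP in cocaine had 833 higher and 1011 lower genes and Q5A vs WT in cocaine 654 and 305, while the other comparisons had at most 9 in all.

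Cocaine was first compared with saline within each virus, to measure the lasting effect of drug taking. Under RFP, 9 genes differed, 8 higher and 1 lower after cocaine. The largest rise was in ENSRNOG00000001254 (chromosome 20, 12773427 to 12801180), at 16.7 ± 5.09 CPM after cocaine and 9.79 ± 2.05 after saline (SD, n = 8 each, log2 fold change 0.75, SE 0.15, edgeR adjusted p = 0.0258). Another, ENSRNOG00000022796 (chromosome 1, 255555050 to 255557055), rose from 5.29 ± 0.925 to 8.82 ± 1.7 CPM (log2 fold change 0.74, SE 0.13, edgeR adjusted p = 0.0169). The gene that fell, ENSRNOG00000011238 (chromosome 2, 157316266 to 157341469), went from 12.6 ± 1.28 to 9.7 ± 2.35 CPM (log2 fold change -0.40, SE 0.08, edgeR adjusted p = 0.0291). In the 16 fits without 1 library, these calls were kept in 7, 12 and 7. In the WT animals all 9 of these genes lay in the same direction and in the Q5A animals 7 did, with a median signed log2 fold change of 0.14 in each against 0.70 under RFP. No gene was called by edgeR between cocaine and saline under WT (990 at an unadjusted p under 0.05; 0 by DESeq2) or under Q5A (1642 unadjusted; 6 by DESeq2), and no interaction showed the cocaine effect to differ between viruses, as given with the interactions.

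The count under RFP was not stable. There were 3042 genes at an unadjusted p under 0.05 and 502 at an adjusted p under 0.1. DESeq2 called 517, of which 115 were higher and 402 lower, but gave an adjusted p to 5694 genes only, and 8 of the 9 edgeR genes had none. Of the 16 libraries, leaving out cocaine RFP replicate 8 raised the edgeR count to 1292 and saline RFP replicate 8 to 394. Leaving out any of saline RFP replicates 1, 2, 3, 4, 5 and 6 or cocaine RFP replicates 2, 3, 4 and 7 lowered it to between 0 and 5. On 416 genes called without lane 4, each RFP library was scored by its mean log2 CPM in the direction of the cocaine effect, after the mean of the other groups of its lane was subtracted, as a distance from the midpoint between the cocaine and saline libraries of lanes 1 to 3. Cocaine RFP replicate 8 scored -0.21, where the saline RFP libraries of those lanes lay between -0.28 and -0.13 and the cocaine ones at 0.13 or above. The genes were chosen on the libraries of lanes 1 to 3, which widens the gap between these ranges. Within lane 4 itself, 56.2% of the 416 genes had the same direction, with a median of 0.01. In that lane cocaine RFP replicate 7, at 0.12, and saline RFP replicate 7, at -0.17, lay on the side of their labels, while saline RFP replicate 8 was at 0.03.

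**Figure D2:**
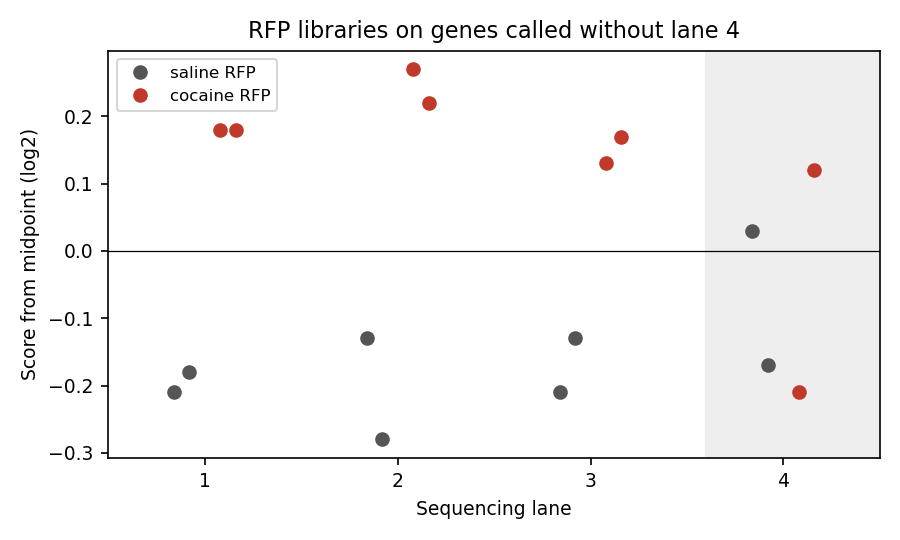
Score of each RFP library, in log2 units from the midpoint of lanes 1 to 3, on the 416 genes called between cocaine and saline without lane 4, by sequencing lane; red points are cocaine and gray points saline libraries. In the shaded lane 4, which took no part in choosing the genes, cocaine RFP replicate 8 stands at -0.21 and saline RFP replicate 8 at 0.03.

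Under Q5A, 332 genes were called between cocaine and saline without saline Q5A replicate 1, and 326 without lane 1, in which it was sequenced. The count was 1 without saline Q5A replicate 2 or cocaine Q5A replicate 4 and 2 without saline Q5A replicate 5.

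Q5A was compared with WT in cocaine animals to ask about the residue, since both viruses carry H3.3. The H3.3 supplied was not measured, so differences in its level or in virus uptake are not separated from the residue. In the Q5A libraries 654 genes were higher and 305 lower. The genes that rose were mostly weakly expressed, 377 of them among the 5000 genes with the lowest level and 75 among the 5000 with the highest, and rose by a median log2 fold change of 0.87. Those that fell were mostly highly expressed, 192 of them among the 5000 highest and 44 among the 5000 lowest, and changed by a median of -0.29. At least 2-fold changes were seen in 279 genes that rose and 18 that fell. ENSRNOG00000024899 (chromosome 14, 15253125 to 15258207) rose most, at 29.5 ± 48.2 CPM with Q5A (n = 7, range 0 to 131) and 0.231 ± 0.185 with WT (n = 8, log2 fold change 6.47, SE 1.18, edgeR adjusted p = 0.00136). It was above every WT library in 5 of the 7 Q5A libraries, and the log2 fold change was 5.17 without cocaine Q5A replicate 3. ENSRNOG00000034190 (chromosome 6, 138054662 to 138662511) stood at 316 ± 425 CPM with Q5A (range 2.82 to 1130) and 4.11 ± 1.3 with WT (log2 fold change 5.92, SE 1.08, edgeR adjusted p = 0.00136). It was above every WT library in 4 of 7, and the log2 fold change was 4.82 without cocaine Q5A replicate 3. It spans 607850 bp and overlaps 12 other genes, so its count is uncertain. Among the genes that fell, ENSRNOG00000008697 (chromosome 7, 94375020 to 94383024) was at 2.92 ± 1.14 CPM with Q5A and 12.1 ± 17.2 with WT (log2 fold change -1.83, SE 0.54, edgeR adjusted p = 0.0303), with 1 WT library, replicate 7, at 53 CPM. Without that library the fold was -1.15, and the call was lost without it or any of cocaine WT replicates 4 and 5 or cocaine Q5A replicates 1, 3 and 7. ENSRNOG00000004642 (chromosome 13, 85918252 to 86061176) was at 5.44 ± 3.54 and 15.8 ± 5.87 CPM (log2 fold change -1.59, SE 0.42, edgeR adjusted p = 0.0157), and below every WT library in 5 of 7 Q5A libraries. This call was lost without cocaine Q5A replicate 3 (-1.41) or cocaine WT replicate 6 (-1.35).

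Q5A was compared with RFP in cocaine animals as the second control. Here 833 genes were higher and 1011 lower, with median log2 fold changes of 0.54 and -0.47, and 224 and 160 of them changed at least 2-fold. The tie to expression level was weaker than against WT: 361 risers and 313 fallers were among the 5000 lowest genes and 187 and 403 among the 5000 highest. ENSRNOG00000034190 rose most here, at 316 ± 425 CPM with Q5A (n = 7) and 4.92 ± 1.26 with RFP (n = 8, log2 fold change 5.73, SE 1.09, edgeR adjusted p = 0.00242). It was above every RFP library in 4 of 7 Q5A libraries and below every one in 1, and the log2 fold change was 4.62 without cocaine Q5A replicate 3. ENSRNOG00000003666 (chromosome 14, 21177237 to 21183542) stood at 25.3 ± 34.5 CPM against 0.477 ± 0.366 (log2 fold change 5.49, SE 0.98, edgeR adjusted p = 0.00205) and was above every RFP library in 4 of 7. The mitochondrial gene ENSRNOG00000031333 (MT, 5185 to 5252, 68 bp) had 0 counts in all 7 cocaine Q5A libraries and 2.44 ± 3.5 CPM with RFP, at least 81.8-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0251), a call lost without cocaine RFP replicate 3 or cocaine Q5A replicate 3. It was present or absent library by library: 3 of 8 cocaine RFP, 1 of 8 cocaine WT, 3 of 8 saline RFP, 0 of 7 saline WT and 4 of 7 saline Q5A libraries held 51 to 127 counts, and all others at most 2. ENSRNOG00000012235 (chromosome 4, 86275717 to 86292431) was at 0.837 ± 0.591 CPM with Q5A and 4.16 ± 2.82 with RFP (log2 fold change -2.23, SE 0.53, edgeR adjusted p = 0.00685).

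In both Q5A comparisons of cocaine animals together, 478 genes rose in both, 199 fell in both and 0 moved in opposite directions. Independent lists of these lengths would share 36.3 and 20.6. The comparisons use the same Q5A libraries. In 8 simulations of unchanged groups, this sharing gave a correlation of fold changes across genes of 0.52 and a covariance of 0.017, with 0 shared calls. The observed correlation was 0.83 and the covariance 0.12, or 0.10 above the simulated. The simulations drew each gene independently, so no simulated library differed from its group in many genes at once. The excess over them is therefore not shown to exceed what shared libraries can give. With the Q5A libraries divided into odd and even replicates, one part for each control, the covariance was 0.083 and 0.095. The odd replicates gave 847 higher and 337 lower genes against WT and 813 and 701 against RFP, and the even ones 7 and 0 against WT and 3 and 1 against RFP, so the calls followed the odd Q5A libraries under either control. The odd part (replicates 1, 3, 5 and 7) was larger than the even part (2, 4 and 6) and held the only cocaine Q5A library of lane 4. The number of libraries, the lane and single libraries were therefore not separated. In either arrangement 1 rise was shared.

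The shared genes were then followed in each library. Scored by their mean log2 CPM relative to the cocaine controls, the 478 shared risers averaged 0.91 ± 0.61 (SD, n = 7) in cocaine Q5A, from 0.06 to 1.76, with the highest control library of cocaine animals at 0.41 and that of saline animals, saline WT replicate 5, at 0.55. The 199 shared fallers averaged -0.45 ± 0.13, from -0.63 to -0.26. These genes were chosen on the cocaine libraries, so the scores describe their spread and are no test there.

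**Figure D3:**
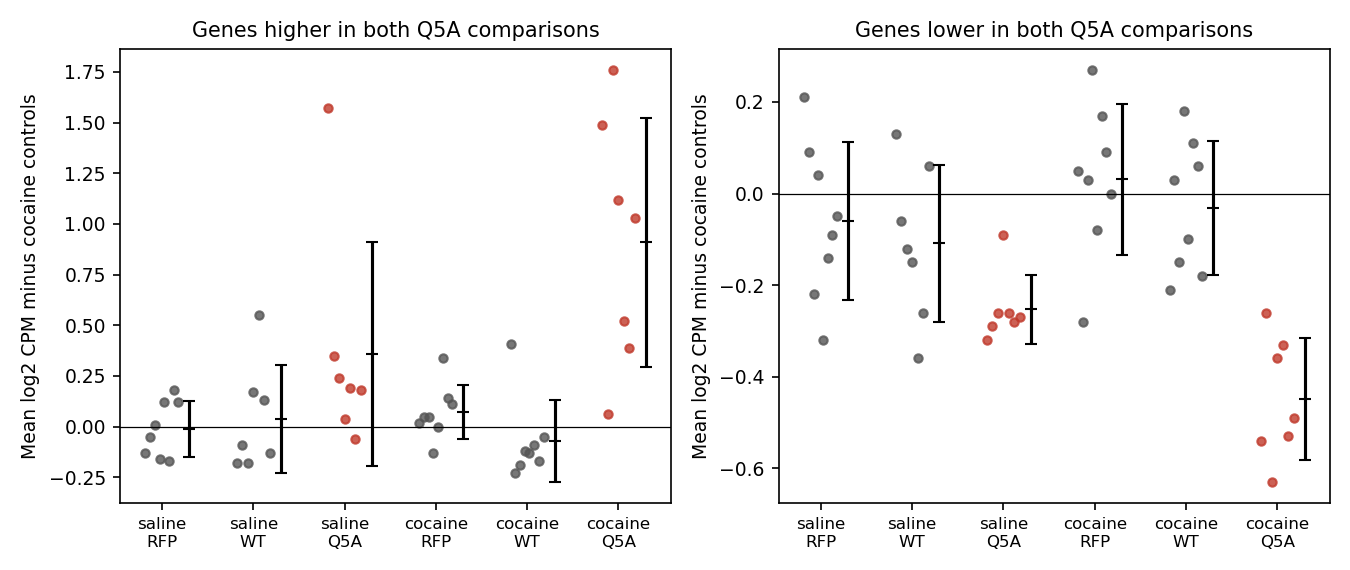
Each point is a library, its height the mean log2 CPM of the 478 genes higher (left) or the 199 lower (right) in both Q5A comparisons of cocaine animals, minus the mean of the cocaine RFP and WT libraries; bars give the mean and SD per group, with Q5A groups in red. Saline Q5A replicate 1 stands at 1.57 on the left, near the highest cocaine Q5A libraries, and the saline Q5A libraries on the right lie between -0.32 and -0.09.

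Both counts depended on few libraries. Q5A vs WT fell to 309 genes without cocaine Q5A replicate 3 and 514 without cocaine Q5A replicate 1, and Q5A vs RFP to 721 and 1192 without the same libraries and 1175 without cocaine RFP replicate 4. The balance of directions moved too. The 305 lower genes of Q5A vs WT became 52 and 90 without cocaine Q5A replicates 3 and 1, 91 without lane 3, 134 to 201 without any of cocaine WT replicates 2, 4, 5, 6 and 7 or cocaine Q5A replicates 4 and 7, and 482 without cocaine WT replicate 1. Q5A vs RFP had 590 higher and 398 lower genes without lane 3, and 913 and 863 without a filter. Without lane 2, which held cocaine Q5A replicates 3 and 4, or with 3 surrogate variables as covariates, at most 1 gene was called in either. Without lane 2 all 654 and 305 genes of Q5A vs WT still had the same direction, with medians of 0.62 and -0.24. The libraries of the remaining lanes also took part in choosing these genes, so the kept direction is no test. Of genes called in the other 3 lanes, the held-out lane gave the same direction for 92.4%, 88.4% and 84.6% with Q5A vs WT (lanes 1, 3 and 4), and 84.1%, 85.8% and 88.5% with Q5A vs RFP. A held-out lane had only 1 or 2 cocaine Q5A libraries, and genes of a library are not independent replicates. These shares were not judged by shuffled labels, so they describe the lanes and are no test.

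WT was compared with RFP in cocaine animals to measure added H3.3 itself, and 2 genes were called. ENSRNOG00000038068 (chromosome 15, 77733402 to 77736892) was higher, at 130 ± 11.3 CPM against 105 ± 16.1 (SD, n = 8 each, log2 fold change 0.32, SE 0.06, edgeR adjusted p = 0.0244). ENSRNOG00000015957 (chromosome 17, 28504623 to 28680362) was lower, at 3.38 ± 0.962 against 6.46 ± 2.43 CPM (log2 fold change -0.89, SE 0.17, edgeR adjusted p = 0.0497). Q5A vs RFP, at 0.34 and -0.90, uses the same RFP libraries, on which these genes were chosen, so its agreement is no separate evidence. The count was 7 without cocaine RFP replicate 8, and 0 or 1 without any of cocaine RFP replicates 1, 3, 4, 5, 6 and 7 or cocaine WT replicates 2, 3, 5, 6, 7 and 8. DESeq2 called 10.

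In saline animals the same viruses were compared as the background without drug. By edgeR no gene was called for Q5A vs WT (876 at an unadjusted p under 0.05; 0 by DESeq2), Q5A vs RFP (1239; 1 by DESeq2) or WT vs RFP (352; 0 by DESeq2). The genes called in cocaine animals lay mostly in the same direction there, although no libraries are shared: 626 of the 654 risers and 267 of the 305 fallers of Q5A vs WT, with medians of 0.30 and -0.09, and 764 of 833 and 875 of 1011 for Q5A vs RFP, with medians of 0.21 and -0.14. This leaned on lane 1: without it, 55% and 74.1% for Q5A vs WT and 71.2% and 71.9% for Q5A vs RFP had the same direction, and without saline Q5A replicate 1, which lane 1 holds, 77.4%, 88.9%, 85.8% and 84.4%. As a set, the 199 shared fallers were lower in saline Q5A than in the 15 saline controls, at -0.25 ± 0.08 against -0.08 ± 0.17 (exact permutation p = 0.023, two-sided; 0.048 adjusted over 4 score tests). All 7 Q5A libraries lay below the mean of the controls, replicate 4 only just, at -0.09. The ranges overlapped, with the lowest control, saline WT replicate 5, at -0.36. The 478 risers were higher, at 0.36 ± 0.55 against 0.01 ± 0.20 (exact permutation p = 0.024; 0.048 adjusted), but without saline Q5A replicate 1 the difference was 0.14 (exact permutation p = 0.13). The fallers without that library were at -0.24 ± 0.08 (exact permutation p = 0.045; 0.06 adjusted). With labels exchanged only within lanes, the adjusted exact p values for fallers were 0.036 with that library and 0.041 without it, and for risers 0.041 and 0.14. On lane-adjusted differences they were 0.04, 0.043, 0.043 and 0.17.

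The interactions asked whether the virus effects differed between cocaine and saline animals. By edgeR no gene was called for Q5A vs WT (817 at an unadjusted p under 0.05; 0 by DESeq2), Q5A vs RFP (975; 2 by DESeq2) or WT vs RFP (545; 0 by DESeq2). The many calls in cocaine animals and none in saline animals are therefore not shown to differ. Without saline Q5A replicate 1, 15 genes were called for Q5A vs WT, and without lane 1, 133.

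Whether Q5A moved the genes of the cocaine history the other way was tested across genes, which are not independent replicates, in pairs of comparisons with no library in common. Fold changes of Q5A vs WT in cocaine and of cocaine vs saline in RFP had r = 0.057, and 27 of 40 splits gave one as large (permutation p = 0.675; 0.872 adjusted). Of the 500 genes with the smallest p in the latter, 34.4% had the opposite sign, and 25 of 40 splits lay as far from 50% (permutation p = 0.625; 0.872 adjusted). Q5A vs RFP in cocaine and cocaine vs saline in WT had r = -0.296 (12 of 40 splits, permutation p = 0.3; 0.675 adjusted) and 60.4% of opposite sign (29 of 40, permutation p = 0.725; 0.872 adjusted). Neither pair stood apart from the splits. The cocaine effect correlated between RFP and WT at r = 0.413, above every other split (1 of 40, permutation p = 0.025, the smallest they can give; 0.225 adjusted), between RFP and Q5A at 0.091 (permutation p = 0.775; 0.872 adjusted) and between WT and Q5A at -0.018 (permutation p = 0.95). The Q5A effect correlated between cocaine and saline animals at 0.446 against WT (permutation p = 0.15; 0.45 adjusted) and 0.543 against RFP (permutation p = 0.05; 0.225 adjusted), but at -0.049 and 0.15 without lane 1. None of the 9 values passed the adjusted threshold.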

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

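The screen of libraries, the thinning, the scores and their tests, and the leaving out of lanes or pairs of libraries were chosen after the results were seen. Of 49 sets of 7 or 8 libraries screened for a library far from the rest of its group, 12 were picked out. The nominal rate of the screen gives about 2.5. Counts and CPM are skewed, and many sets are genes chosen for large folds in these libraries, so an excess over chance is not shown.

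In the risen genes, saline Q5A replicate 1 scored 1.57 against -0.06 to 0.35 in the other saline Q5A libraries, and cocaine WT replicate 1 scored 0.41 against -0.23 to -0.05. In the fallen genes, saline Q5A replicate 4 scored -0.09 against -0.32 to -0.26. ENSRNOG00000024899 was at 131 CPM in cocaine Q5A replicate 3 and at most 51.8 in the others, and ENSRNOG00000003666 was at 95 CPM in cocaine Q5A replicate 1 and at most 39.3. ENSRNOG00000008697 was at 53 CPM in cocaine WT replicate 7 and at most 14 in the others, and ENSRNOG00000034190 was at 6.88 CPM in cocaine WT replicate 2 and at most 4.61. ENSRNOG00000012235 was at 2.02 CPM in cocaine Q5A replicate 4 and at most 0.989. Saline WT replicate 2 held 32381595 counts against at most 15261281, and cocaine WT replicate 5 held 19376446 against at most 13207736. The mitochondrial share was 6.62% in saline RFP replicate 1, with 7.63% to 8.4% in the others, and 9.03% in cocaine WT replicate 2, with 7.5% to 8.08% in the others.

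The rise with Q5A in cocaine animals: with all libraries thinned to equal depth, 709 higher genes were called for Q5A vs RFP, against 833 before, which argues against depth. RNA of other cells in some libraries would leave some Q5A libraries near the controls, and 5 of 7 lay above the highest cocaine control (4 above saline WT replicate 5, the highest control of all at 0.55), so it stays open, as does uneven uptake of the virus, which was not tested. With 3 surrogate variables the median log2 fold change of the 654 risers of Q5A vs WT went from 0.87 (median SE 0.21) to 0.15 (0.20), so the calls ended because the folds shrank, and these variables hold 84.1% of the variance of the risen score. The Q5A virus itself stays open, since saline Q5A without replicate 1 was not separated from the saline controls (adjusted exact p from 0.13 to 0.17 in 3 forms of the test).

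The fall with Q5A in cocaine animals: 851 lower genes were called for Q5A vs RFP after thinning, against 1011 before, which argues against depth in that comparison. For Q5A vs WT the lower genes went from 305 to 203 with thinning, so a part of depth stays open there. Dilution by the RNA that rose would spare libraries with little of the rise. The 6 saline Q5A libraries other than replicate 1 lay below the saline controls, at an adjusted exact p of 0.06 with labels exchanged freely, 0.041 within lanes and 0.043 on lane-adjusted differences, so dilution cannot be told apart from other causes, as the outcome turns on the form of the test. An effect of the Q5A virus itself remains a hypothesis. The mean score of the 7 saline Q5A libraries was below that of the saline controls (adjusted exact p at most 0.048 in all 3 forms), with overlapping ranges. With 3 surrogate variables the median log2 fold change of the 1011 fallers went from -0.47 (median SE 0.13) to -0.11 (0.11).

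The difference between cocaine and saline under RFP: on 416 genes called without lane 4, cocaine RFP replicate 8 scored -0.21, inside the saline range of lanes 1 to 3 (-0.28 to -0.13) and outside the cocaine range, which starts at 0.13. The genes were chosen on the libraries of lanes 1 to 3, which widens the gap between those ranges. Cocaine RFP replicate 7 of lane 4, at 0.12, also lay outside the cocaine range. A wrong label on cocaine RFP replicate 8 is a candidate explanation, and an animal that took little cocaine would look the same. Neither is stated in the labels. An exchange with saline RFP replicate 8 cannot be told apart from no exchange, as that library scored 0.03, between both ranges. The part of the 3 deeper libraries with another title form cannot be told apart either: without them 3 of the 9 calls were kept and the median signed log2 fold change went from 0.70 to 0.59, against 0.60 to 0.74 without any of the 27 other pairs of saline RFP libraries, on genes chosen with all of them.

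Shuffling group labels within lanes in 40 splits, the real one included, asked how often as many genes are called. For 3 comparisons 1 of 40 splits, the real one, reached the real count: Q5A vs RFP in cocaine (1844 genes, highest other split 3), Q5A vs WT in cocaine (959, highest other 534) and WT vs RFP in cocaine (2, highest other 1). This is the smallest share that 40 splits can give, and adjusted over the 12 comparisons it is 0.1, which does not pass. Taken singly, the share of 0.025 for Q5A vs RFP is under 0.05, and its count stayed at 721 or more without any single library. That count was 0 without lane 2 and 1 with 3 surrogate variables, so chance is not taken as excluded there. Chance is also not taken as excluded for Q5A vs WT. Its count falls below that of another split without cocaine Q5A replicate 3 (309) or 1 (514). The same holds for WT vs RFP, whose count falls to 0 or 1 without most single libraries. Chance could not be excluded for cocaine vs saline under RFP (9 genes), which 2 of 40 splits reached. There the highest other split called 218 genes, and under Q5A, with 0 real calls, another split called 209. Splits that call several times the real number point to a structure of the samples, which was not identified. For the comparisons with 0 calls all 40 splits reached the real count: the highest other was 0 for cocaine vs saline under WT, 2, 0 and 0 for Q5A vs WT, Q5A vs RFP and WT vs RFP in saline, and 1, 2 and 1 for the interactions of Q5A vs WT, Q5A vs RFP and WT vs RFP.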

How the results depend on the processing

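Leaving out lanes or the 5 least correlated libraries and thinning were chosen after the data were seen. No gene named in the text changed sign under any of the settings run, though these settings reuse libraries that chose the genes. Of 376 such values 254 were counted as keeping their call and 122 lost it. The 254 include DESeq2 values with no adjusted p, for the genes named under RFP and for ENSRNOG00000015957. Some folds nearly vanished with 3 surrogate variables, as in ENSRNOG00000004642 (Q5A vs WT, -1.59 to -0.09). Others moved little, as in ENSRNOG00000001254 (cocaine vs saline in RFP, 0.75 to 0.65). RLE scaling kept every count within 1.5 times. In the order cocaine vs saline in RFP, Q5A vs WT, Q5A vs RFP and WT vs RFP in cocaine, against 9, 959, 1844 and 2 genes, the fit of only the groups compared called 0, 356, 982 and 0, which has fewer samples; 3 surrogate variables 1, 0, 1 and 1; no lane 2 called 0 in all; no lane 4 416, 547, 887 and 1; and without the 5 libraries 2, 184 and 103 for the first 3. DESeq2 called 517 in RFP and 10 for WT vs RFP; no lane term 4 and 0; no other title form 4 and 0; thinning 3 and 0; no lane 1 1 and 0; no lane 3 1, 988 for Q5A vs RFP and 0. The stricter filter called 23 in RFP and no filter 4 for WT vs RFP. Comparisons with 0 genes gained some: cocaine vs saline in Q5A 6 with DESeq2, 12 without a filter, 8 without the 5 libraries and 326 without lane 1; Q5A vs RFP in saline 1 with DESeq2 or without lane 3; the interaction of Q5A vs RFP 2 with DESeq2 and of Q5A vs WT 133 without lane 1.

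Leaving out 1 library gave 0 to 1292 genes in RFP, 309 to 1274 for Q5A vs WT and 721 to 2392 for Q5A vs RFP in cocaine, 0 to 7 for WT vs RFP in cocaine, 0 to 332 for cocaine vs saline in Q5A, 0 to 1 for Q5A vs RFP in saline and 0 to 15 for the interaction of Q5A vs WT. The 5 libraries include the Q5A libraries that score highest in the risen genes. Leaving them out therefore cannot tell an effect of Q5A from a trait of those libraries. Of the correlations, those that moved by more than the SD over splits are given first. Q5A vs RFP in cocaine with cocaine vs saline in WT went from -0.296 to -0.016 without a filter, -0.043 with surrogate variables and -0.036 without lane 3. The cocaine effect in RFP and WT went from 0.413 to 0.091, 0.158 and, without lane 2, 0.224. Q5A vs RFP in cocaine and saline went from 0.543 to 0.16 with surrogate variables, 0.256 without the 5 libraries and 0.15 without lane 1, and Q5A vs WT from 0.446 to -0.049 without lane 1. Within that SD, the last also went to 0.163 with surrogate variables and 0.265 without a filter, the first to -0.073 without lane 2 and -0.087 without the 5 libraries, Q5A vs RFP in cocaine and saline to 0.297 without a filter, and the cocaine effect in RFP and WT to 0.234 without the 5 libraries. The r of 0.057 changed sign, to -0.093 without the other title form and -0.065 without lane 1, and was at most 0.237, without the 5 libraries. Those of 0.091 and -0.018 ran from -0.001 to 0.162 and from -0.147 to 0.106. Surrogate variables shrank the folds; elsewhere the cause was not tested. The gene lists, the H3.3 check and tissue composition as covariates were not run, for want of symbols. Thinning to 7673963 counts kept the total counts of Q5A vs WT and Q5A vs RFP in cocaine within 1.5 times, but not the lower genes of Q5A vs WT (305 to 203). Depth limits weakly expressed genes most.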

Other observations

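All tests in this part were chosen after the data were seen. Several of the genes that rose with Q5A vs WT in cocaine animals lay close together. Of 1139 windows of 1 Mb, 4 held more of the 654 risers than their number of tested genes gives (hypergeometric test, adjusted over windows). Chromosome 20 from 4000001 to 5000000 held 7 of 17 tested genes, with a median log2 fold change of 4.72 (adjusted p = 0.0044). Chromosome 4 from 157000001 to 158000000 held 10 of 44 (median 1.19, adjusted p = 0.0085) and from 163000001 to 164000000 4 of 7 (median 2.08, adjusted p = 0.032), and chromosome 2 from 248000001 to 249000000 held 4 of 6 (median 1.54, adjusted p = 0.019). Q5A vs RFP, which shares the Q5A libraries, called 5, 6, 3 and 4 genes of these windows in the same direction, with none of its windows of risers past the threshold. Neighbouring genes, and reads shared between near-identical copies, are not independent, so these p-values are too small. No window stood out among the 305 genes lower in Q5A vs WT.

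Among the 1011 genes lower with Q5A vs RFP in cocaine animals, chromosome X from 107000001 to 108000000 held 6 of 9 tested genes, with a median log2 fold change of -0.31 (adjusted p = 0.0074). Over the whole X chromosome 65 of 524 tested genes were lower, or 12.4% against 6.7% of all tested genes, though camera did not set the chromosome apart in this comparison (adjusted p = 0.36, or 0.9 with an estimated correlation), and Q5A vs WT called 14 lower on it. For Q5A vs RFP in saline animals camera placed the X chromosome lower (median -0.03, adjusted p = 0.029, or 0.93 with an estimated correlation), with 0 genes called by edgeR (1239 over all chromosomes at an unadjusted p under 0.05; 1 by DESeq2). The 25 tested mitochondrial genes had a median log2 fold change of -0.18 for cocaine vs saline in RFP (camera adjusted p = 4.5e-05), 0.19 for WT vs RFP in cocaine (1.3e-08), 0.20 for Q5A vs RFP in cocaine (0.0039) and -0.12 for Q5A vs WT in saline (0.047). With an estimated correlation the adjusted p values were 0.62, 0.59, 0.9 and 0.92, and by fry 0.11, 0.15, 0.25 and 0.94. All but the last of these comparisons use the same cocaine RFP libraries, so they are not separate evidence. The mitochondrial share of counts was 6.97% ± 0.52 in cocaine RFP (SD, n = 8) and 7.74% ± 0.51 in saline RFP (n = 8). It averaged 7.64% in saline WT, 7.3% in saline Q5A, 7.94% in cocaine WT and 7.84% in cocaine Q5A.

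Averaged over cocaine and saline animals, Q5A differed from the mean of both control viruses in 1928 genes, 996 higher and 932 lower. No library was left out for this count, and it is not shown to hold in saline animals, where Q5A vs WT and Q5A vs RFP had 0 calls by edgeR (876 and 1239 at an unadjusted p under 0.05; 0 and 1 by DESeq2). The H3.3 viruses together differed from RFP in 85, 16 higher and 69 lower. The last contrast includes Q5A, which alone had 1844 calls against RFP in cocaine animals, while WT vs RFP had 2 there and 0 in saline animals by edgeR (352 at an unadjusted p under 0.05; 0 by DESeq2), so it is not shown to be common to both. Lane itself differed in 4643 of the 15000 tested genes.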
